A study of Rattus norvegicus with 19 samples.

How the data were processed

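Gene expression was measured on a rat Affymetrix array in 19 samples of total RNA from F344/N rats. Per the labels, 6 samples came from a culture of normal Fred-PE mesothelial cells, 5 from spontaneous mesotheliomas and 8 from mesotheliomas of animals exposed to vinylidene chloride (VDC). Per the labels, frozen tissue was homogenized, RNA was treated with DNase on a column, and biotin-labelled RNA was made with a 3' IVT kit. The labels do not say whether samples of a group came from separate animals or cultures. The deposited table holds 1 intensity value per probe set and array, which the authors made with MAS5 per the submitters' processing notes. The version, the background settings and any filter are not given in the sources used here. The values were linear and never negative, and every array had the same mean after the lowest and highest 2% of values were left out (about 500), as a scaling of whole arrays gives. The table held 31099 probe sets with no missing values, of which 57 control probe sets were left out of the gene tests and 31042 were tested.

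Signals were used as log2(signal + 16) with no further normalization. The median signal was 99.1 in the culture, 149.2 in spontaneous and 147.4 in VDC tumours, so genes with low signal have compressed fold changes. Precision comes from the 5 to 8 arrays per group and the spread between them. The median SD of a probe set was 0.41 on the log2 scale in the culture, 0.26 in spontaneous and 0.35 in VDC tumours. Each log2 fold change is given with its standard error (SE) from the fit where its precision matters.

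Probe sets were named from the annotation of the array platform, where 20826 carried 1 gene symbol, 436 several and 9780 none. Of the gene identifiers, 20758 were matched by identifier to the rat reference annotation (GRCr8), which gave the current symbol, and 68 were not matched and kept the platform's symbol. This gave 14217 genes, 4525 of them with more than 1 probe set. A gene's value was that of its brightest probe set by mean over all arrays.

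There were 3 comparisons, each tumour group against the culture and VDC against spontaneous tumours. Each used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the arrays of the 2 groups alone, because cultured cells and tumours can vary by different amounts. Adjusted p-values are Benjamini-Hochberg values over all probe sets tested, and probe sets with an adjusted p under 0.05 were called. Genes that rose or fell were counted by their brightest probe set alone, and genes called in both directions over all their probe sets. Gene lists were fixed before the data were examined: 38 lists with 545 genes, of which 481 were measured. They were tested with camera of limma at a preset inter-gene correlation of 0.01, two-sided, on 1 probe set per gene, with adjustment over the 38 lists. Members were also adjusted over their list alone. Quality measures per array were compared with exact permutation tests. Calls shared by both tumour groups were set against 20 simulations and against a split of the cultures between the comparisons. Each simulation drew all arrays from the cultures' means with each group's spread, so unchanged tumours shared 1 set of simulated cultures. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

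Genes were named by a rule fixed before the data were examined. It took, per comparison, the 8 largest rises and 8 largest falls among called genes with a proper single symbol that moved the same way in every tumour, up to 3 members with the smallest adjusted p of each list called or described, and 24 genes chosen in advance. Of these 24, Upk3b was not named on the array. For 1 more of these genes and 1 of the 38 lists, results are not reported here.

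Alternatives fixed before the data were examined were a pseudocount of 1 or 64, quantile normalization, centring of each array on its median, leaving out the dimmest 40% of probe sets, and a log2 fold change of at least 1. Others were 1 probe set per gene, the mean of a gene's probe sets, all 3 groups in 1 fit, an intensity trend with a robust fit, array weights per group and the ratio of 3' to 5' Gapdh probe sets as a covariate. The replicate number as a block and each array left out in turn were tried too. Lists were also tested with an estimated inter-gene correlation, with fry, and by permutation of list scores. After seeing the data, 3 were added: the arrays of the block without the block term, skeletal muscle and adipocyte scores as covariates between the tumour groups, and leaving out the 1013 probe sets that correlated with the muscle score at 0.7 or more across tumours in the comparisons with the culture.

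The pipeline was tested on simulated data drawn from each probe set's own mean and spread, with 200 changed probe sets among 31042. All 200 were taken from probe sets brighter than the median, so recovery was not measured for dimmer ones. For spontaneous tumours against the culture it recovered 14.9% of changes of 1.5-fold, 49.2% of 2-fold and 83.3% of 4-fold. For VDC tumours against the culture these were 17.9%, 67.2% and 86.4%, and between the tumour groups 31.3%, 77.6% and 95.5%. The share of false calls was 9.26%, 13.6% and 8.72% in the same order. A shifted complement list was called in each comparison, with 0 other lists called. Each probe set was drawn independently, so list members did not correlate, and the 0 says nothing about lists of correlated genes. Survival, pathology and dose were not analysed here.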

Results

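Mesotheliomas that arose spontaneously in F344/N rats, mesotheliomas from rats given vinylidene chloride (VDC), and a culture of normal rat mesothelial cells named Fred-PE were compared on 19 expression arrays: 6 of the culture, 5 of spontaneous tumours and 8 of VDC tumours. The first principal component of all arrays carried 47.5% of the variance and the next 13.4%. Within groups, the median correlation between arrays was 0.938 in the culture, 0.961 in the spontaneous tumours and 0.954 in the VDC tumours. No label places the samples in separate animals or cultures, so p-values measure the spread between these samples. No normal mesothelial tissue was sampled, so tumour against normal and tissue against cells in culture cannot be told apart in comparisons with the culture. Fold changes are differences of log2(signal + 16) and understate genes near the background.

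Spontaneous mesotheliomas carried a broad set of transcripts that mesothelial cells in culture lacked, among them genes of immune and vascular cells. MHC class II, macrophage, mast cell and endothelial genes rose together with interferon-responsive and complement genes, and targets of the Hippo pathway fell. Of 31042 probe sets tested with limma, 8669 passed an adjusted p of 0.05 (27.9%), 5617 of them higher and 3052 lower in the tumours, where 12043 had an unadjusted p under that limit. In genes, 2443 rose and 1657 fell of 14217, and 59 had probe sets called in both directions.

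All 8 measured genes of MHC class II presentation rose in spontaneous tumours, with a median log2 fold change of 7.21 (camera adjusted p = 3.48e-10, and 0.0475 with an estimated correlation). Cd74, the chaperone of class II molecules, rose by 9.51 ± 0.22 (SE, adjusted p = 2.17e-10), RT1-Da by 8.28 ± 0.25 (adjusted p = 1.88e-09) and RT1-Ba by 8.14 ± 0.42. Of 16 macrophage markers, 15 rose (16 adjusted over the list alone; median 6.83, camera adjusted p = 3.37e-21, and 0.0265 with an estimated correlation). Among them Aif1 gained 7.53, the complement subunit C1qa 7.91, the lysozyme gene Lyz2 8.67 and the scavenger receptor Cd163 5.90. All 9 mast cell markers rose (median 6.11, adjusted p = 9.5e-13, and 0.0265 with an estimated correlation), led by the proteases Mcpt10 at 7.90, Cpa3 at 6.87 and Cma1 at 6.31. Ccl11, a chemokine that draws eosinophils, had the largest rise of these genes at 9.64 ± 0.25 (adjusted p = 4.76e-10) and was higher in all 5 tumours than in all 6 cultures.

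T and NK cell markers rose in 14 of 16 genes (16 over the list alone), with Cd3d at 4.16, Cd3e at 3.60 and Cd5 at 2.82. The list's median was 2.77 (camera adjusted p = 6.93e-10), and its adjusted p was 0.221 with an estimated correlation. Of 23 interferon response genes, 20 rose (median 2.76, adjusted p = 3.57e-11, and 0.0265 with an estimated correlation), among them the antiviral genes Oas1a (4.29), Oas1b (4.12) and Mx1 (3.75) and the chemokine Cxcl10 (3.18 ± 0.89, adjusted p = 0.0196). Without spontaneous replicate 2 the adjusted p of Cxcl10 was 0.0516. Ubd, a ubiquitin-like gene that interferon induces, rose by 8.43 ± 0.78. MHC class I presentation rose in 9 of 10 genes (median 2.05, adjusted p = 2.38e-05, and 0.222 with an estimated correlation), with the peptide transporter genes Tap1 and Tap2 at 2.38 and 2.55 and the class I regulator Nlrc5 at 3.83. Complement rose in 8 of 9 genes (median 2.01, adjusted p = 1.96e-05, and 0.0478 with an estimated correlation), with the inhibitor Serping1 at 8.21 and C6 at 2.01. Of 12 endothelial markers, 9 rose (median 2.91, adjusted p = 1.1e-08, and 0.0366 with an estimated correlation), including Plvap (4.50), Pecam1 (4.48) and Emcn (3.83).

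Mesothelial and epithelial genes shifted in part. The keratin gene Krt19 rose by 9.03 ± 0.23 (adjusted p = 4.76e-10) from near the background in all 6 cultures to 14.28 ± 0.05 (SD) in the tumours, and Thbd, the gene of thrombomodulin, rose by 4.81 ± 0.60. Of 17 mesothelial markers, 5 rose and 1 (Rspo1, -1.51 ± 0.22) fell, with a median of 1.37 (camera adjusted p = 0.0219, and 0.381 with an estimated correlation). This call rested on culture replicate 1, without which the list's adjusted p was 0.103 while 8 members rose and 3 fell. Wt1 (1.37 ± 0.78, adjusted p = 0.221), Msln (0.54 ± 0.62, adjusted p = 0.57) and Calb2 (0.57 ± 0.51, adjusted p = 0.455) did not pass. Culture replicate 1 was far below the other cultures in Wt1 (8.31 against 12.35 to 13.22) and Msln (10.31 against 13.75 to 14.27), which widened their spread. Epithelial junction genes rose in 5 of 12 (median 0.91, adjusted p = 0.028, and 0.227 with an estimated correlation), with Epcam at 4.37, Dsc2 at 3.75 and Cldn3 at 1.40. Cldn3 no longer passed after median centring (adjusted p = 0.057).

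**Figure D1:**
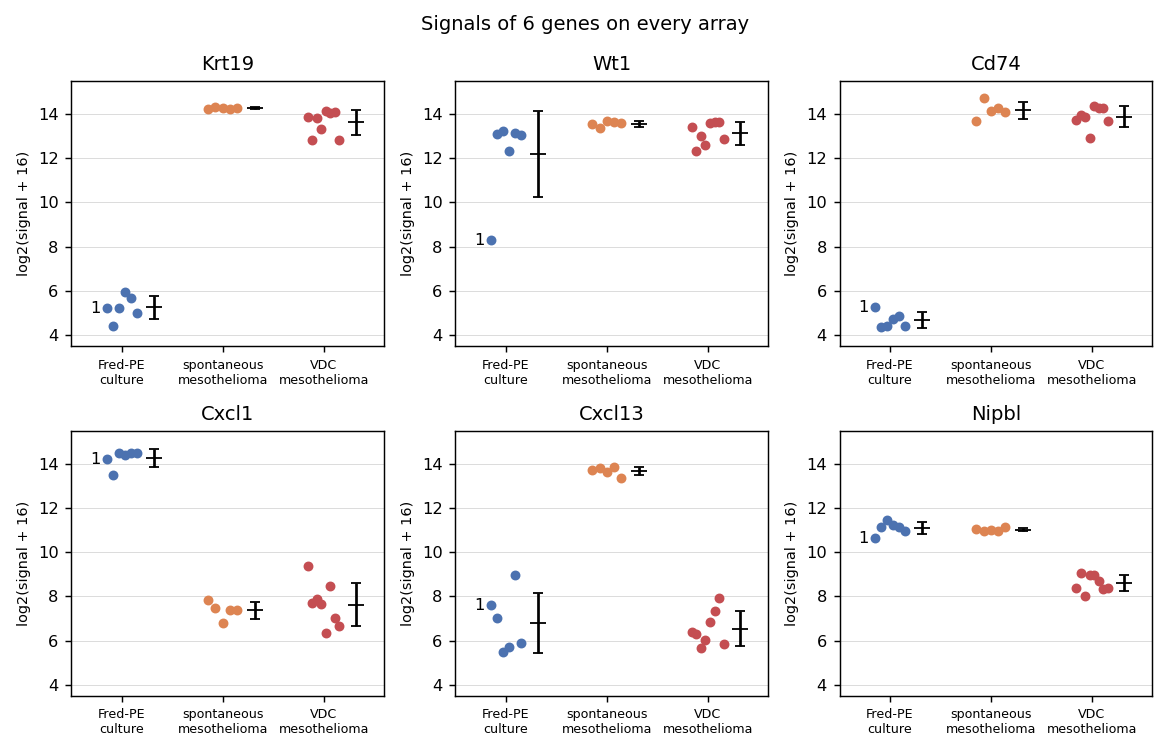
Log2(signal + 16) of 6 genes on each of the 19 arrays (1 point per array, black marks are the mean and SD, and the digit 1 marks culture replicate 1). Krt19 averaged 5.25 in the culture and 14.28 and 13.63 in spontaneous and VDC tumours, Cxcl1 averaged 14.26 in the culture and 7.36 and 7.63 in the tumours, and Cxcl13 averaged 13.68 in spontaneous tumours against 6.54 in VDC tumours.

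In spontaneous tumours immediate early genes fell in 10 of 12 (11 over the list alone; median -2.45, camera adjusted p = 1.57e-08, and 0.187 with an estimated correlation), with Fosb at -5.33 ± 0.71, Fos at -3.15, Ier3 at -2.51 and Dusp1 at -2.11. Hippo pathway targets fell in 9 of 12 (10 over the list alone; median -1.85, adjusted p = 9.66e-08, and 0.0265 with an estimated correlation), with Ccn1 at -5.57 ± 0.28 (adjusted p = 7e-08), the coagulation factor receptor F3 at -4.32 and Ccn2 at -4.01. All 11 cholesterol synthesis genes fell (median -1.62, adjusted p = 6.16e-09, and 0.187 with an estimated correlation), including Fdps (-2.15), Sqle (-2.20) and Insig1 (-1.93). Inflammatory transcripts of the culture were among the largest falls: the neutrophil chemokine Cxcl1 at -6.90 ± 0.23 (adjusted p = 3.19e-09), the prostaglandin synthase Ptgs2 at -5.76 ± 0.62 and Ccl20 at -4.92 ± 1.32. The cytochrome gene Cyp1b1 (-6.00 ± 0.36), the elastin gene Eln (-5.09 ± 1.03) and the collagen hydroxylase gene P4ha3 (-4.95 ± 0.28) fell as well.

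TGF-beta pathway genes fell in 7 of 15 and rose in 1, led by Tgfb2 (-4.03 ± 0.39, adjusted p = 1.51e-05) and the inhibitor Smad7 (-3.04 ± 0.17), against Tgfbr1 at 0.99. The list's median was -0.04, its mean -0.79 and its camera adjusted p 0.0412. This call ended with an estimated correlation (adjusted p = 0.221) and under quantile normalization (0.135). Nrf2 and xenobiotic metabolism genes fell in 5 of 19 (6 over the list alone) and rose in 1 (median -0.76, adjusted p = 0.0182, and 0.227 with an estimated correlation), among them Nqo1 (-2.94) and Gclc (-1.65). Of 10 ribosomal protein genes, 2 fell (median -0.26, adjusted p = 0.00904, and 0.546 with an estimated correlation), Rpl4 (-0.42) and Rpl18 (-0.49), but 0 without culture replicate 2 and 5 without culture replicate 1. Neither of these genes passed after quantile normalization (adjusted p = 0.168 and 0.134). Hypoxia and glycolysis genes rose in 8 of 15 (median 0.66, adjusted p = 0.0476, and 0.296 with an estimated correlation), with Pfkp at 2.59, Bnip3 at 1.69 and Ldha at 0.66. Ldha did not pass after median centring (adjusted p = 0.42).

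Growth and tumour suppressor genes moved in both directions or not past the threshold. Of 27 growth factor and receptor genes, 5 rose and 5 fell (7 and 8 over the list alone; camera adjusted p = 0.693), with Igf1 at 4.55 ± 0.92 (adjusted p = 0.00309) and Igfbp6 at 3.16 against Hbegf at -2.14 and the receptor Igf1r at -1.97. Egfr (-0.03), Met (0.10) and Igf2 (-1.99 ± 1.51, adjusted p = 0.367) did not pass. Of 10 mesothelioma tumour suppressors, Rb1 rose (0.79 ± 0.21) and 2 fell, Lats2 (-0.95) among them (adjusted p of the list = 0.257). Nf2 (-0.09), Bap1 (0.02), Cdkn2b (-1.61 ± 0.80, adjusted p = 0.16) and Cdkn2a (-0.68 ± 1.46, adjusted p = 0.774) did not pass, and Cdkn2a varied between cultures with an SD of 3.61. Cdkn2b was far lower in culture replicate 6 (4.68) than in the other cultures (7.99 to 9.69), which widened its spread. Of 25 proliferation genes, Tyms alone rose (1.35) and none fell (camera adjusted p = 0.0541), and Mki67 (-0.25) and Top2a (-0.58) did not pass. Without culture replicate 1, the culture with the lowest proliferation score, 19 of these genes fell and 1 rose.

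Matrix, cytokine and tissue lists were mixed. Of 17 fibroblast and collagen matrix genes, 4 rose and 3 fell (camera adjusted p = 0.745), with Col6a1 at 6.95 ± 0.90 and Col6a3 at 6.63 ± 0.61 against Col5a2 at -0.95. Matrix proteases and inhibitors rose in 5 (1 without culture replicate 5) and fell in 3 of 17 (adjusted p = 0.807), with Lox, which cross-links collagen, at -1.96 and the urokinase receptor gene Plaur at -2.03. Of 21 inflammatory cytokines and NF-kB targets, 7 rose and 6 fell (adjusted p = 0.769), with Il1rn at 5.11 and Il1b at 2.05 against Cxcl1 and Ptgs2, while Il6 (-2.50 ± 1.23, adjusted p = 0.156) and Ccl2 (-0.13) did not pass. In the Wnt pathway 3 of 17 genes rose, Wnt4 (3.58) and Tcf7 (1.56) among them, and 1 (Fzd2, -1.44) fell (adjusted p = 0.693). Adipocyte markers rose in 5 of 9 (7 over the list alone, 8 without spontaneous replicate 1; median 2.61, adjusted p = 0.00148, and 0.381 with an estimated correlation), with Cfd at 7.12, Fabp4 at 6.19 and Lpl at 4.18. Skeletal muscle markers (1 of 12 rose, adjusted p = 0.0541) were high in 2 of the 5 tumours. Neutrophil markers rose in 4 of 7 (adjusted p = 0.0757), erythroid markers in 2 of 5 (0.0711), B and plasma cell markers in 2 of 8 (0.137), steroidogenic and Sertoli cell markers in 3 of 9 (0.382) and liver and pancreas markers in 3 of 11 (0.677). Smooth muscle (2 rose and 2 fell of 9, 0.769), DNA repair (1 rose and 1 fell of 13, or 6 fell without culture replicate 1, 0.391), oxidative phosphorylation (1 fell of 16, 0.0639), germ cell (1 fell of 8, 0.769), Schwann and neural (0 of 5, 0.578) and sex-linked (0 of 3, 0.945) lists did not pass by camera.

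Of the 38 lists, 19 passed by camera in spontaneous tumours and 7 of these also with an estimated correlation. Without culture replicate 1 the adjusted p rose to 0.104 for the TGF-beta pathway and 0.107 for epithelial junctions, and without spontaneous replicate 2 to 0.0782 for hypoxia and glycolysis. The 2 groups did not overlap in 6095 probe sets (19.6%), against a chance share of 0.433%. The cultures' median signal was 99.1 ± 4.05 (SD) and that of the spontaneous tumours 149.2 ± 4.63 (exact permutation test, two-sided p = 0.00216), so the balance of rises and falls depends on the scaling. In the deposited scaling 64.8% of the called probe sets rose. After quantile normalization it was 40.01%, and after median centring 19.1%, where the median of all probe sets moved from 0.05 to -0.48. No called gene or list named above reversed direction in either scaling.

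In VDC mesotheliomas macrophage, mast cell and complement genes rose over the culture and targets of the Hippo pathway fell. The bioB spike, which holds no rat RNA, was lower on their arrays than on the culture's (5.82 against 9.30). Where spontaneous tumours did not share a difference, separate array processing and the tumours themselves cannot be told apart. With limma, 11441 of 31042 probe sets passed (36.9%; 14096 unadjusted), 6783 higher and 4658 lower, or 3107 genes that rose and 2472 that fell. In 169 genes probe sets were called in both directions. Macrophage markers rose in all 16 genes (median 6.97, camera adjusted p = 1.28e-22, and 0.00565 with an estimated correlation), with Cd163 at 7.43 ± 0.35 and Lyz2 at 8.40. All 9 mast cell markers rose (median 5.72, adjusted p = 1.24e-10, and 0.00953 with an estimated correlation), with Cpa3 at 6.81 and the IgE receptor gene Fcer1a at 4.84, and complement rose in 8 of 9 genes (median 2.92, adjusted p = 4.45e-06, and 0.0306 with an estimated correlation). The 8 class II genes (median 6.83, adjusted p = 2.53e-10, and 0.0684 with an estimated correlation), 21 of 23 interferon response genes (2.76, 2.53e-10, and 0.123), all 16 T and NK cell markers (2.79, 1.63e-08, and 0.0925), 11 of 12 endothelial markers (3.39, 1.59e-07, and 0.123) and 9 of 10 class I genes (1.89, 0.000215, and 0.305) rose too. Cd74 gained 9.22, Ubd 8.88, Ccl11 8.82, the phospholipase gene Pla2g2a 8.61 and Krt19 8.38 ± 0.28, each higher in all 8 tumours than in all 6 cultures.

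In VDC tumours immediate early genes fell in 11 of 12 (median -2.57, camera adjusted p = 1.49e-08, and 0.111 with an estimated correlation), with Fosb at -5.16, Junb at -3.01 and Egr1 at -2.79. Hippo pathway targets fell in 10 of 12 and rose in 1 (median -2.00, adjusted p = 1.41e-06, and 0.0306 with an estimated correlation), with Ccn1 at -4.92 and Amotl2 at -2.34. Cholesterol synthesis fell in all 11 (median -1.49, adjusted p = 1.91e-08, and 0.0925 with an estimated correlation) and ribosomal proteins in all 10 (median -0.46, adjusted p = 1.83e-05, 0.305 with an estimated correlation and 0.335 after quantile normalization). TGF-beta pathway genes fell in 7 of 15 and rose in 2 (median -0.41, adjusted p = 0.0268, 0.123 with an estimated correlation and 0.149 after median centring). Cxcl1 (-6.63 ± 0.39), Ptgs2 (-5.21 ± 0.62), Eln (-4.98 ± 0.87), Mycn, a growth-promoting transcription factor gene (-4.83 ± 0.64), P4ha3 (-4.81) and Ccl20 (-4.75) had the largest falls beside Fosb and Ccn1. Proliferation passed as lower by camera (median -0.79, adjusted p = 0.00305, and 0.654 with an estimated correlation) although 1 of 25 genes (Plk1, -1.74) fell, and without culture replicate 1 it was 21.

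Skeletal muscle markers rose in 11 of 12 genes (median 6.18, camera adjusted p = 7.13e-05, and 0.35 with an estimated correlation), with the titin gene Ttn at 7.33 and Myl11 at 7.61, and adipocyte markers in all 9 (median 4.80, adjusted p = 6.13e-05, and 0.305 with an estimated correlation), with Cfd at 8.45 and Fabp4 at 7.93. Erythroid markers rose in 3 of 5 (adjusted p = 0.0132, and 0.305 with an estimated correlation), with Hbb at 8.85, neutrophil markers in 4 of 7 (0.0165, and 0.305), with S100a9 at 4.55, and hypoxia and glycolysis genes in 8 of 15 (0.0173, and 0.305), with Bnip3 at 2.53 and Hk2 at 1.04. Mesothelial markers (6 rose and 1 fell of 17, adjusted p = 0.0731), epithelial junctions (6 of 12 rose, 0.0695) and Nrf2 and xenobiotic metabolism (3 rose and 6 fell of 19, 0.122) did not pass. Without culture replicate 1, 6 mesothelial markers rose and 6 fell. Fibroblast and collagen matrix (6 rose and 4 fell of 17, 0.6), growth factors (10 rose and 5 fell of 27, 0.854), cytokines and NF-kB targets (8 and 6 of 21, 0.854), matrix proteases (4 and 5 of 17, 0.854), the Wnt pathway (3 and 2 of 17, 0.854) and tumour suppressors (1 and 3 of 10, 0.149) held rises and falls. Also not past the camera threshold were the B and plasma cell (3 of 8 rose, 0.105), liver and pancreas (4 of 11 rose, 0.278), steroidogenic and Sertoli cell (1 of 9 rose, 0.272), DNA repair (1 rose and 1 fell of 13, or 5 fell without culture replicate 1, 0.184), oxidative phosphorylation (2 of 16 fell, 0.575), smooth muscle (2 rose and 1 fell of 9), germ cell (1 of 8 fell), Schwann and neural (1 of 5 rose) and sex-linked (1 of 3 rose) lists, the last 4 with an adjusted p of 0.854 each.

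Among genes fixed in advance, Igf1 (5.72 ± 0.86, adjusted p = 0.000109), Cxcl10 (3.15), Cd3e (2.69) and Met (0.83 ± 0.20, adjusted p = 0.00452) rose and Tgfb2 (-3.21 ± 0.31) fell in VDC tumours. Met did not pass after median centring (adjusted p = 0.224). Cdkn2b fell (-2.01 ± 0.71, adjusted p = 0.0366), a call that ended without culture replicate 4 (adjusted p = 0.0839). Wt1 (0.93), Msln (-0.04), Calb2 (0.76), Mki67 (-0.51), Top2a (-0.79), Cdkn2a (-1.05), Nf2 (-0.24), Bap1 (-0.12), Egfr (-0.94 ± 0.37, adjusted p = 0.061), Igf2 (-0.69), Il6 (-2.45 ± 0.97, adjusted p = 0.061), Ccl2 (-0.67), Col1a1 (-1.93) and Cyp2e1 (-0.40) did not pass. Col1a1 (-1.90) and Cyp2e1 (-0.94) did not pass in spontaneous tumours either. Single cultures lay far from the rest in some of these genes, which widened their spread, so such results do not show an absence of change. These were replicate 1 in Wt1, Msln, Mki67 and Top2a, replicate 3 in Col1a1 (7.68 against 13.6 to 14.56) and replicate 5 in Cyp2e1 (12.05 against 5.81 to 7.03). Of the 38 lists, 20 passed by camera and 4 of these with an estimated correlation. Without culture replicate 1 the TGF-beta pathway (adjusted p = 0.0877) no longer passed. Groups did not overlap in 4624 probe sets (14.9%, chance share 0.0666%). In the deposited scaling 59.3% of the called probe sets rose, after quantile normalization 37.7% and after median centring 19.97%, with the median of all probe sets at -0.45. The median signal was 147.4 ± 6.91 (SD), against 99.1 in the culture (exact permutation test, two-sided p = 0.000333).

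**Figure D2:**
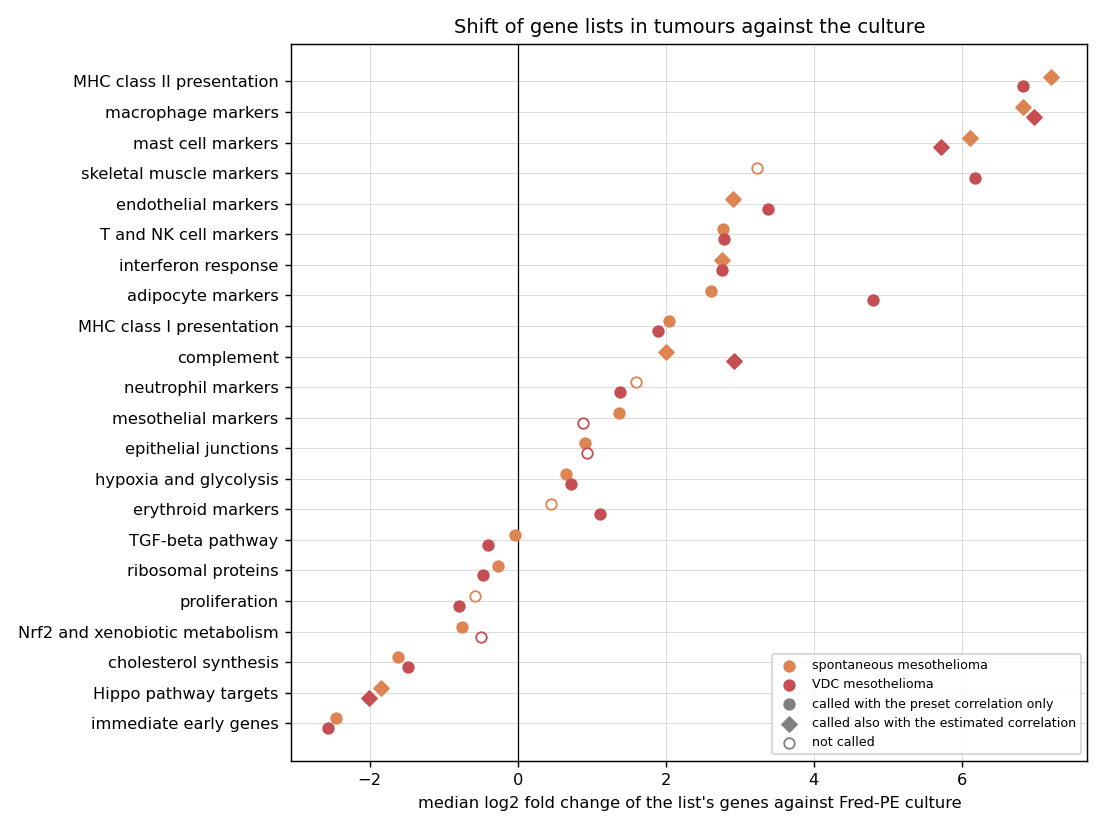
Median log2 fold change against the culture of gene lists that passed by camera in either tumour group (1 point per list and group; diamonds passed also with an estimated correlation, open circles did not pass). MHC class II presentation stood at 7.21 and 6.83 in spontaneous and VDC tumours, skeletal muscle markers at 3.23 and 6.18, Hippo pathway targets at -1.85 and -2.00 and immediate early genes at -2.45 and -2.57.

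The tumour groups shared most of their difference from the culture. Of the 8669 probe sets called in spontaneous tumours, 6845 (79.0%) were called in the same direction in VDC tumours, 4425 higher and 2420 lower, Cd74, Krt19, Cxcl1 and Ccn1 among their genes. Both comparisons used the same 6 cultures, so differences between tissue and cells in culture would be shared too and cannot be told apart from tumour traits. In 20 simulations of unchanged tumours, which shared simulated cultures, 0 probe sets were shared. That count decides nothing, since with no true change hardly any probe set can be called. Simulated fold changes correlated at 0.649, against 0.898 observed. With the cultures split 3 and 3 between the tumour groups, 4252 and 4823 probe sets were shared. Another 1795 were called in spontaneous tumours only and 4567 in VDC tumours only, and 824 of the latter also differed between the tumour groups. For calls in VDC tumours only, separate array processing cannot be told apart from the tumours. In 29 probe sets the directions were opposite.

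VDC and spontaneous mesotheliomas differed from each other in fewer genes, and the widest difference was in a B cell chemokine. The bioB spike was lower on all 8 VDC arrays than on all 5 spontaneous ones. For every difference in this comparison, separate array processing and the tumours therefore cannot be told apart. Cxcl13 averaged 13.68 ± 0.20 (SD) in spontaneous tumours and 6.54 ± 0.78 in VDC tumours, a log2 fold change of -7.14 ± 0.33 (SE, adjusted p = 1.87e-07), with all 8 VDC tumours below all 5 spontaneous ones and near the culture's 6.78. With limma, 2430 of 31042 probe sets passed (7.83%; 7314 unadjusted), 711 higher and 1719 lower in VDC tumours, or 290 genes that rose and 544 that fell. In 23 genes probe sets were called in both directions. The count of probe sets was 1487 without spontaneous replicate 4 and 1595 with all 3 groups in 1 fit. Dio3, which inactivates thyroid hormone (-3.66 ± 0.90, adjusted p = 0.0243), the connexin gene Gjb2 (-2.77 ± 0.67, adjusted p = 0.0211), Rgs7bp (-2.44 ± 0.60) and the secreted glycoprotein gene Chi3l1 (-2.42 ± 0.52, adjusted p = 0.0114) fell beside Cxcl13. Without spontaneous replicate 4, the adjusted p was 0.0618 for Dio3, 0.0582 for Gjb2 and 0.0696 for Rgs7bp. Other genes were lower in all 8 VDC tumours than in all 5 spontaneous ones. Nipbl, which loads cohesin on chromosomes, fell (-2.42 ± 0.17, adjusted p = 4.43e-06), as did Bod1l1 (-2.40 ± 0.38) and the corepressor gene Rcor1 (-2.38 ± 0.25, adjusted p = 0.000101).

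Among genes higher in VDC than in spontaneous tumours, the haemoglobin gene Hba-a3 rose by 3.03 ± 0.67 (adjusted p = 0.0134) and Hbb by 0.97 ± 0.23 (adjusted p = 0.0184), with 1 of 5 erythroid markers past the threshold (2 over the list alone; median 0.97, camera adjusted p = 0.035, and 0.875 with an estimated correlation). Without spontaneous replicate 4 the adjusted p of Hbb was 0.0599. S100a8, a calcium-binding protein of neutrophils, rose by 2.77 ± 0.55 (adjusted p = 0.00724) and S100a9 by 2.04 ± 0.58 (adjusted p = 0.0477, and 0.112 without spontaneous replicate 1), while the list of 7 did not pass (0.199). The oxygenase gene Fmo1 (2.19 ± 0.56) and the cytochrome gene Cyp4b1 (1.86 ± 0.49) rose, both above the threshold without spontaneous replicate 5 (adjusted p = 0.077 and 0.0834), as did Slc25a48 (2.44 ± 0.48), Enpp3 (1.94 ± 0.31, adjusted p = 0.00202) and Plac8 (1.94 ± 0.43). Of 19 Nrf2 and xenobiotic genes 1 rose (2 over the list alone), the glutathione transferase gene Gsta1 (1.47 ± 0.33, adjusted p = 0.0138, and 0.0964 for the list). Cd163 rose by 1.53 ± 0.44 (adjusted p = 0.0484, and 0.114 without spontaneous replicate 1).

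Signalling genes told the tumour groups apart in small numbers. In the Wnt pathway 3 of 17 genes fell in VDC tumours, the feedback inhibitor Axin2 (-1.19 ± 0.18, adjusted p = 0.00133), the receptor Fzd1 (-1.30 ± 0.26, adjusted p = 0.00742) and Wnt11 (-1.53 ± 0.38, adjusted p = 0.026, and 0.0769 without spontaneous replicate 5), with a camera adjusted p of 0.781 for the list. Egr1 (-0.85 ± 0.19) and Junb (-0.64 ± 0.17, adjusted p = 0.0339, and 0.0904 without spontaneous replicate 5) were the 2 of 12 immediate early genes that fell (list 0.538). Egfr fell (-0.91 ± 0.25, adjusted p = 0.038) and Met rose (0.73 ± 0.20, adjusted p = 0.0373). Neither passed after median centring (0.0564 and 0.0558), and the growth factor list had an adjusted p of 0.492. The tumour suppressor Rb1 rose by 0.87 ± 0.21 (adjusted p = 0.0232, and 0.0734 without spontaneous replicate 4), in a list with an adjusted p of 0.702. Mesothelial markers were lower by camera (median -0.48, adjusted p = 0.016, and 0.875 with an estimated correlation). Of its 17 genes Lrrn4 alone passed (-0.68 ± 0.18, adjusted p = 0.0317, and 0.0856 without spontaneous replicate 5). The list's score was 10.5 to 10.99 in VDC replicates 2, 3, 4 and 9. It was 11.45 to 11.76 in VDC replicates 1, 6, 7 and 8, near the 11.56 to 11.77 of spontaneous tumours. A link to muscle and fat transcripts, which also varied between VDC tumours, was not tested for this list. Ribosomal proteins were lower (median -0.21, adjusted p = 0.0022, 0.875 with an estimated correlation and 0.496 after quantile normalization), with 0 of 10 past the limma threshold and 3 over the list alone. Adipocyte markers were higher (median 1.74, adjusted p = 0.016, and 0.875 with an estimated correlation) with 0 of 9 past it and 0 over the list alone. Without spontaneous replicate 1 the adjusted p was 0.0722 for adipocyte and 0.0774 for erythroid markers. Col6a1 (-0.70 ± 0.15) and Col6a3 (-1.06 ± 0.25) fell and Fbn1 (1.29 ± 0.34) rose among the 17 matrix genes, whose median was -0.20 and mean 0.23 (camera adjusted p = 0.527). Without spontaneous replicate 5 the adjusted p was 0.062 for Col6a3 and 0.0908 for Fbn1.

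The lists that separated both tumour groups most strongly from the culture were not shown to differ between the tumours. Macrophage (camera adjusted p = 0.904), T and NK cell (0.538), mast cell (0.468), MHC class II (0.492) and class I (0.323), interferon (0.825), complement (0.333), endothelial (0.0625), Hippo pathway (0.333) and cholesterol synthesis (0.925) lists did not pass. Neither did proliferation (0.0964), skeletal muscle (0.0578), smooth muscle (0.308), B and plasma cell (0.882), steroidogenic and Sertoli cell (0.702), germ cell (0.882), liver and pancreas (0.527), Schwann and neural (0.527), sex-linked (0.527), cytokine and NF-kB (0.983), TGF-beta (0.527), DNA repair (0.527), hypoxia and glycolysis (0.384), epithelial junction (0.323), matrix protease (0.602) and oxidative phosphorylation (0.323) lists. Of the 38 lists 4 passed by camera, 0 with an estimated correlation, 0 by fry and 0 by exact permutation of list scores. Fixed genes that did not pass were Wt1 (-0.44), Msln (-0.57), Calb2 (0.20), Mki67 (-0.26), Top2a (-0.21), Cdkn2a (-0.37), Cdkn2b (-0.40), Nf2 (-0.14), Bap1 (-0.13), Igf1 (1.17), Igf2 (1.30), Tgfb2 (0.81), Il6 (0.05), Ccl2 (-0.53), Ptgs2 (0.55), Cxcl10 (-0.03), Cd3e (-0.91), Col1a1 (-0.02) and Cyp2e1 (0.54).

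Muscle and fat transcripts varied between tumours of each group. Skeletal muscle scores reached 13.41 and 13.82 in spontaneous replicates 1 and 3 and stayed within the cultures' 5.51 to 6.82 in the other 3. They were 12.50 to 14.12 in 6 VDC tumours but 7.66 and 6.19 in VDC replicates 6 and 8. With muscle and fat scores as covariates, a fit chosen after seeing the data, 1151 probe sets differed between the tumour groups in place of 2430, and 1011 of these were among the 2430. Spike controls that hold no rat RNA differed too. The bioB spike averaged 5.82 ± 0.07 (SD) on VDC arrays against 9.30 ± 0.05 on spontaneous and 9.30 ± 0.09 on culture arrays (exact permutation tests, two-sided p = 0.000777 and 0.000333). Spontaneous and culture arrays differed in the spikes lys (6.975 against 7.655) and phe (7.688 against 8.257). By the same test over 15 array measures the adjusted p was 0.0162 and 0.0243, and bioC, bioD, cre, dap and thr did not pass. The log2 3' to middle Gapdh ratio was 0.556 in VDC tumours and 0.425 in the culture (exact permutation test, adjusted p = 0.0343). The 3' to 5' Gapdh ratio and both beta-actin ratios did not pass. The 2 tumour groups did not overlap in 1685 probe sets (5.43%, chance share 0.155%). The number of arrays limits precision, and single genes near the threshold depended on 1 array.

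**Figure D3:**
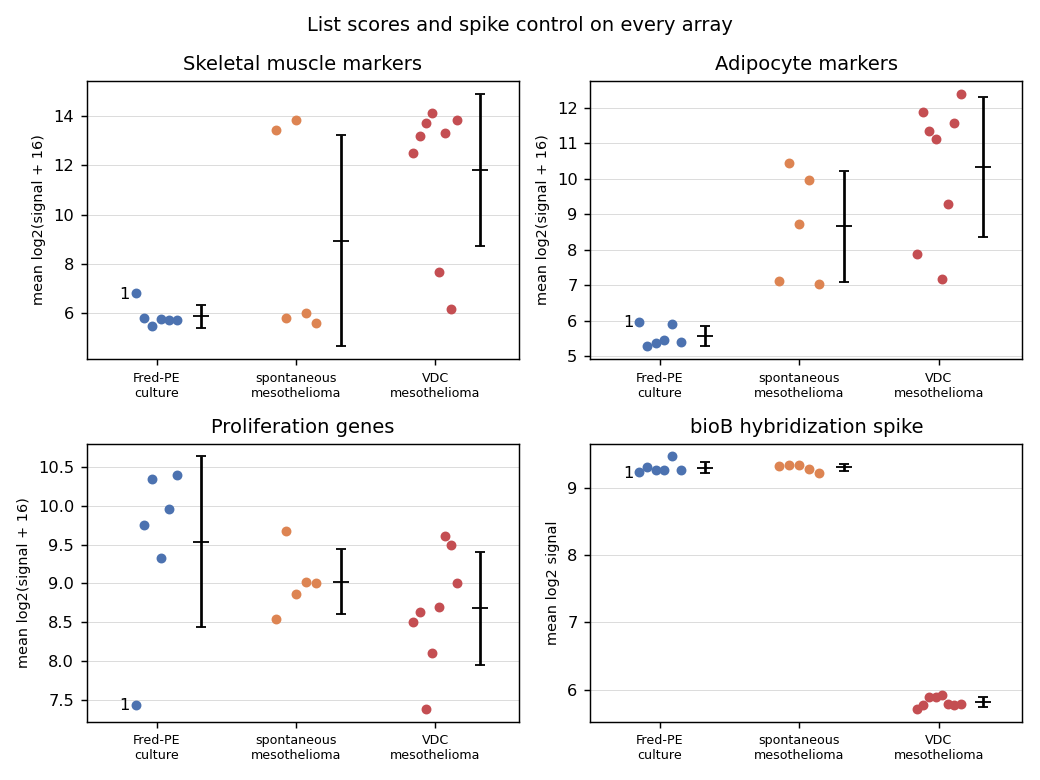
Mean log2(signal + 16) of skeletal muscle, adipocyte and proliferation genes and mean log2 signal of the bioB spike on each array (1 point per array, black marks are the mean and SD, and the digit 1 marks culture replicate 1). Muscle scores ran from 5.63 to 13.82 in spontaneous tumours, culture replicate 1 had the lowest proliferation score of the cultures at 7.43, and the spike was lower on all 8 VDC arrays (5.71 to 5.91) than on the others.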

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

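Tests chosen after seeing the results were those on culture replicate 1, those of rises and falls apart, of rises by size and of 3 immune lists under median centring, the probe-set test, and the fit with muscle and fat scores as covariates. The level of the bioB spike was a planned quality measure, but its use as a test was chosen after it was seen. The comparisons, gene lists, naming rule and other tests were fixed before the data were examined.

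Each gene, list and array measure named in the text was tested in each group for a single array far from the others. Of 534 such tests 60 found one, where chance gives about 1 in 20 (26.7). Of these arrays 34 were cultures, and culture replicate 1 alone gave 13.

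Culture replicate 1 stood apart from the other 5 cultures. Mesothelial genes were low (Wt1 8.31 against 12.35 to 13.22, Msln 10.31 against 13.75 to 14.27, Lrrn4 9.19 against 12.93 to 13.72), as were growth genes (proliferation score 7.43 against 9.34 to 10.4, Mki67 6.93, Top2a 7.11, Tyms 7.27), Rpl4 (13.78) and Bod1l1 (7.52). The smooth muscle score (10.12 against 6.92 to 7.97), skeletal muscle score (6.82), Col6a3 (9.62 against 5.72 to 6.49) and Hbb (6.98) were high. A mislabelled tumour was argued against by its macrophage score of 5.32, where tumours ran from 11.4 to 12.54. RNA integrity, another cell type in the dish and a changed state of the same cells stayed open, since its log2 3' to 5' ratio was the lowest of the cultures for beta-actin (0.81, others up to 2.12) but the highest for Gapdh (0.18, others 0.01 to 0.15), and no biological explanation was tested.

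Other cultures were far from the rest in single measures. In culture replicate 3 the Y-linked gene Eif2s3y was 4.77 against 11.61 to 12.03, the sex-linked score 6.45 against 8.82 to 9.40, Col1a1 7.68 against 13.6 to 14.56, Gsta1 6.68 against 12.01 to 13.31 and the Nrf2 and xenobiotic score 9.12. Culture replicate 2 was low in Cxcl1 (13.48), Cyp1b1 (11.32), Fosb (8.60 against 12.01 to 13.55) and the cytokine and NF-kB score (6.75 against 8.31 to 8.84). Culture replicate 5 was high in Cyp2e1 (12.05 against 5.81 to 7.03), Fabp4 (6.56), Emcn (6.31), Oas1b (4.93), the complement score (7.95) and the bioB spike (9.46 against 9.23 to 9.31). Culture replicate 4 was high in F3 (14.19) and the Hippo pathway score (12.38), and culture replicate 6 was high in Wnt4 (10.22) and low in Cdkn2b (4.68 against 7.99 to 9.69) and in the spikes dap (9.44 against 10.47 to 10.8) and thr (7.28 against 8.10 to 8.48).

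Among spontaneous tumours, replicate 1 was low in Ubd (9.06 against 13.66 to 14.34), Serping1 (13.32), Tap2 (9.55), Cldn3 (4.85), Rgs7bp (7.88 against 10.02 to 10.62) and Axin2 (7.69) and high in Oas1b (9.21). Replicate 2 was low in Ccl11 (13.39), Igfbp6 (13.09) and Lats2 (11.55) and high in Plac8 (13.53 against 10.43 to 10.85) and the ribosomal protein score (14.26), and replicate 5 was high in Dusp1 (12.57) and Fzd1 (11.19). Among VDC tumours, replicate 4 was low in Cd74 (12.91), RT1-Da (12.68), Il6 (4.19), Egr1 (10.51) and the germ cell score (4.59) and high in Fosb (7.50). Replicate 2 was high in Cyp2e1 (9.49), S100a8 (11.89 against 8.15 to 9.72) and the neutrophil score (8.34), replicate 3 was high in Ccl20 (6.09), replicate 1 was low in the lys spike (6.76) and replicate 9 was low in the epithelial junction score (7.90).

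The balance of rises and falls against the culture depended on the scaling of the arrays. After median centring 71.44% of the probe sets called in spontaneous and 71.82% of those called in VDC tumours were called in the same direction, between the limits of 50% and 80% set for and against array scaling as the cause. Of the rises 55.92% and 52.47% were kept and array scaling and biology cannot be told apart for the rises as a whole, because the median signals of the groups differed. Keeping 82.51% and 83.72% of rises by 1 or more, 2.67% and 4.42% of smaller ones, and 100% and 100% of falls decides nothing, since a shift of all values by -0.52 and -0.51 largely fixes these outcomes. The macrophage, mast cell and MHC class II lists were chosen for their large rises, so their test could hardly fail. Of their 33 measured genes 96.97% (95% interval 84.24 to 99.92) and 100% (89.42 to 100) were called as higher after centring. List medians were then 5.21 to 6.69, so these rises were larger than the shift, which decides nothing for other genes.

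The effects of the tumour groups against the culture were tested for opposite directions, and 29 probe sets were called in both with opposite signs. Of these 23 were higher in spontaneous and lower in VDC tumours and 6 the reverse, and all 29 also differed between the tumour groups (highest adjusted p = 0.00681). A second probe set of Nipbl was among them, at 0.82 in spontaneous and -1.22 in VDC tumours against the culture, chosen for mention after its values were seen.

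VDC tumours were lower than spontaneous ones in 1719 probe sets and higher in 711. Muscle and fat in the tumours stayed open as a cause. With their scores as covariates the median absolute log2 fold change of the called probe sets kept 88.67% of its size (0.80 before, 0.71 after). The calls went from 2430 to 1151. The kept size decides little, since transcripts that follow muscle or fat varied widely within groups and were hardly called. Of the skeletal muscle markers 0 of 12 passed, and of the adipocyte markers 0 of 9. Of 143 probe sets that rose by 1 or more, 53 had other probe sets of the same gene above the median signal. In 49 of the 53 (92.45%, 95% interval 81.79 to 97.91) the others moved the same way on average. This argued against a purely probe-set-specific effect for these 53. The others moved less, with a median of 0.56 against 1.205, so a part of such an effect stayed open. Of 619 that fell by 1 or more, 257 had other such probe sets, and 192 agreed (74.71%, 68.93 to 79.9). The others' median was -0.33 against -1.35, and that effect stayed open. The bioB spike differed by -3.48 between the groups and its levels did not overlap, so separate array processing and a difference between the tumours cannot be told apart. Exposure to VDC and differences between the animals stayed open as untested explanations.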

How the results depend on the processing

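Of the settings, the arrays of the replicate block without its term, the muscle and fat covariates and the fit without muscle-correlated probe sets were chosen after seeing the data, and the others before the data were examined. Unless said otherwise the cause of a change was not tested. A log2 fold change of at least 1 left 4764 probe sets in spontaneous and 5722 in VDC tumours against the culture, 762 between the tumour groups and 3691 shared, by construction. The test on 1 probe set per gene called 4198, 5684 and 677 genes, because fewer units were tested. Median centring gave 16438 and 17825 calls against the culture and 13522 shared, because it moved the tumours' values down. All 3 groups in 1 fit gave 1595 between the tumour groups, and muscle and fat covariates gave 1151. An estimated inter-gene correlation left 7 and 4 lists against the culture and 0 between the tumour groups, where quantile normalization left 1, fry 0 and permutation of the list score 0 of 4. Pseudocounts, the filter on dim probe sets, intensity trend, array weights, the Gapdh covariate and the fit without muscle-correlated probe sets kept every count they were run on within 1.5 times.

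With the replicate block 6360 probe sets were called in spontaneous tumours against the culture, 6467 in VDC tumours against the culture and 406 between the tumour groups, where 9 lists were called. The same arrays without the block term gave 7990, 8375 and 1440, so part of the loss came from fewer arrays. Against the culture the numbers did not pair the samples: 0 of 5 and 0 of 5 pairs with the same number had deviations that correlated over 0.1. There 1 and 0 correlated best with their own number. Between the tumour groups pairing stayed open, since 2 of 4 pairs correlated over 0.1 (from -0.31 to 0.375) and 3 correlated best with their own number.

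With 1 array left out, calls ran from 7112 to 10149 (without spontaneous replicate 3 and without culture replicate 1), from 10432 to 12266, and between the tumour groups from 1487 (without spontaneous replicate 4, and 1491 without spontaneous replicate 5) to 2944 (without VDC replicate 6). Shared calls ran from 5841 to 8012, and lists from 16 to 22, from 19 to 22 and from 3 to 6. The number of genes that rose or fell in a list moved by over 1.5 times in 76 of 228 counts, by 1 or 2 genes in 66 of them and by more in 10, growth factors between the tumour groups among these (1 rose, 4 without VDC replicate 6). No called gene or list named in the text reversed, and 1 called probe set did, in VDC tumours against the culture under median centring. Of 222 results on single genes, 20 lost their call under the replicate block, 15 with 1 array left out, 8 under quantile normalization, 7 under median centring, 6 with a pseudocount of 1, 5 with all groups in 1 fit, 3 with the mean of probe sets and 1 with a pseudocount of 64. Calls were gained by 10 under median centring, 5 with a pseudocount of 64, 4 with all groups in 1 fit, 3 each under quantile normalization and the replicate block, and 1 with the mean of probe sets. Of 114 results on lists, 32 lost their call with an estimated correlation, 9 with 1 array left out, 8 under quantile normalization, 6 under median centring, 5 by fry, 5 by permutation, 3 without dim probe sets, 1 under the block and 1 with the mean of probe sets. Calls were gained by 14 by permutation, 13 by fry, 8 under median centring, 7 under the block, 3 under quantile normalization, 2 without dim probe sets and 1 each with either pseudocount and the mean of probe sets. Signals near the background limit small fold changes, since the median signal was 99.1 in the culture and 149.2 and 147.4 in the tumours.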

Other observations

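The tests in this part were planned, except for the count of probe sets without a gene symbol, which was chosen after seeing the results. Genes that told the tumour groups apart held different places against the culture. Cxcl13 rose in spontaneous tumours over the culture by 6.91 ± 0.55 (adjusted p = 3.18e-06) and was not shown to differ in VDC tumours (-0.24 ± 0.52, adjusted p = 0.757). Dio3 rose in both, by 7.14 ± 0.24 (adjusted p = 3.19e-09) and by 3.48 ± 0.82 (adjusted p = 0.00379), and it was 11.87 to 13.02 in the 5 spontaneous but 6.18 to 11.3 in the 8 VDC tumours. Chi3l1 also rose in both, by 7.86 ± 0.19 and 5.44 ± 0.47, as did Plac8 by 6.24 ± 0.53 and 8.17 ± 0.25 and Enpp3 by 2.66 ± 0.80 and 4.60 ± 0.68. Wnt11 rose in spontaneous tumours (1.48 ± 0.50, adjusted p = 0.0444) and stood at -0.05 in VDC tumours. Gjb2 passed in neither (1.58 and -1.20).

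Other genes were not shown to differ from the culture in spontaneous tumours but passed in VDC tumours, each by its brightest probe set. Nipbl, of which another probe set was higher in spontaneous tumours (0.82), was at -0.08 ± 0.15 (adjusted p = 0.743) and fell by 2.50 ± 0.18 (adjusted p = 1.06e-07), Rcor1 was at -0.43 and fell by 2.82 ± 0.26 (adjusted p = 1.17e-06), and Bod1l1 was at 0.31 and fell by 2.09 ± 0.36. Axin2 was at 0.03 and fell by 1.16 ± 0.30 (adjusted p = 0.00738), Rgs7bp was at 0.63 and fell by 1.81 ± 0.52, and Slc25a48 was at 0.18 and rose by 2.62 ± 0.47 (adjusted p = 0.000476). Mycn fell in spontaneous tumours by 4.66 ± 0.82 (adjusted p = 0.00133), near its fall in VDC tumours.

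Chance as the source of the number of called probe sets was tested with 100 splits of the same arrays into groups of the same sizes. In spontaneous tumours against the culture 1 of 100 splits, the real one, reached 8669, and the highest other split called 4331. In VDC tumours against the culture it was 1 of 100, with 11441 against 4302, and between the tumour groups 1 of 100, with 2430 against 2202. In each comparison only the real split reached its count, which argued against chance, but 100 splits cannot show a share below 1 in 100. Between the tumour groups the margin over the highest other split was small. The split with 4331 calls was the real grouping with culture replicate 3 moved to the tumours. In the split with 4302 calls, culture replicate 1 and VDC replicate 4 had changed places. The split with 2202 calls set spontaneous replicate 1 and VDC replicates 2, 3, 4 and 9 apart from the other 8 tumours, 4 of them VDC, so it was not close to the real grouping, and what those 5 tumours shared was not tested. The next highest other split called 3.

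Between the tumour groups, array scaling and RNA integrity stayed open. After median centring 83.87% of called probe sets stayed called, which decides nothing because the median signals of the tumour groups were close (147.4 and 149.2) and centring moved the median fold change by little. With the 3' to 5' Gapdh ratio as a covariate the median absolute log2 fold change kept 99.73% of its size, which decides nothing because that ratio averaged 0.11 in both tumour groups, and the ratio of the 3' to the middle Gapdh probe set was 0.56 in VDC and 0.45 in spontaneous tumours (exact permutation test, two-sided p = 0.0544). Of the 619 probe sets that fell by 1 or more in VDC tumours, 235 (37.96%) had no gene symbol, against 31.51% of all probe sets tested (Fisher exact test, two-sided p = 0.00064). Of those that rose by 1 or more it was 19.58% (Fisher exact test, two-sided p = 0.00203). The other hybridization spikes differed between VDC and spontaneous arrays by -0.46 (bioC), -0.29 (bioD) and -0.34 (cre), and the spikes dap, thr, lys and phe by 0.78, 0.53, 0.51 and 0.13.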
